A study of Mus musculus with 2 samples.

How the data were processed

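The samples are 2 single-cell libraries of mouse blood cells, 1 from young (2 months) and 1 from old (24 months) animals labelled male. Per the labels, red cells were lysed, live CD45+ CD11b+ Ly6G+ cells were sorted, and cells were captured with the BD Rhapsody system, with a cell barcode and a UMI on each molecule. The deposited values are UMI counts per gene and cell barcode, not normalized. Cell Ranger 7.2.0 is named in the file headers and Cell Ranger with build mm10 in the submitters' processing notes. Neither states the annotation release or how cells were called. Barcodes in the files have 16 bases, each with at least 500 UMIs, and the labels do not say how they relate to Rhapsody cell labels. The files list 32285 genes. Positions of the named genes came from the GENCODE annotation of GRCm38, the build named mm10 in the notes, and all 153 of them matched by gene identifier.

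Cells with at least 200 genes and at most 20% mitochondrial UMIs were kept, which removed 678 young and 817 old barcodes. Both libraries were clustered together without batch integration in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2). Counts were scaled to 10000 UMIs per cell and log-transformed. The steps used 2000 variable genes per library, 30 principal components, 15 neighbours and Leiden resolution 0.6. A cluster was named "X-like" from 16 marker lists fixed beforehand, with at least 3 markers detected and leading genes that do not go against the name. A marker counted as detected at 20 CPM and 25% of its highest cluster. These limits, the minimum of 20 cells per named cluster and the rule that kept a cluster of low-level leading genes unnamed were set after the data were seen. Immature and interferon-stimulated neutrophil clusters counted as neutrophil-like.

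Scrublet, run per library, called 1 young cell and 0 old cells doublets, so the caller has not worked and no doublets were removed from the main result. Neutrophil-like cells with at least 0.5% of UMIs from markers of T, NK, B, platelet or erythroid cells numbered 189 young (1.92%) and 321 old (3.69%), and were left out in an alternative.

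UMIs were summed over neutrophil-like cells per library and given as CPM, and ratios are log2 of old over young CPM with 1 CPM added to each. The shift of the median gene was taken over genes at 50 CPM or more in the mean of the libraries. Members of the 35 gene lists, fixed before the data were examined with a further list to check the labels, were measured at 5 CPM or more in that mean. They were counted as higher or lower from 1.5-fold. Each list's median was placed among those of 10000 random lists of the same size matched on expression, as a description. The text names the 12 genes with the largest and the 12 with the smallest ratio among those at 50 CPM or more in either library, without mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes or unnamed models. It also names up to 4 members of each list at 10 CPM or more by size of ratio, and Cxcr4, Cxcr2, Cdkn1a, Il1b, Cxcl2, Ly6g, Itgam, Mmp9, S100a8 and S100a9 whatever their values. Lcn2, Cdkn2a, Xist, the Y-linked genes and the genes of the classical monocyte-like cells were named outside this rule. Not every gene that this rule gave is reported here.

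Score shares were taken after thinning each cell to 1000 UMIs with a fixed seed. Values within clusters were taken for neutrophil-like clusters with at least 200 cells of each library. Free RNA was judged from UMIs per B cell-like cell, a level that also holds any doublets of B cells and neutrophils. For Sugct it was judged from the S100a8 UMIs per cell of each type, as a share of the neutrophil-like level. The interval of a list median in another cell type is the 95% range over 200 Poisson redraws of the summed counts. For this comparison the ratio step was tested on simulated data over 5748 genes and the list step over 7173, with counts drawn at the real depths. Of the genes changed 2-fold and 4-fold, 100% lay beyond 1.5-fold on the right side relative to the simulated median gene. Intervals held the true value in 92% to 98% of these genes. No shift of the median gene was simulated, whereas in the data it stood at -0.68 log2. The simulation thus does not test the plain calls under such a shift. Among 200 simulated lists without change, 9.5% lay outside the 5th to 95th percentile. Simulated cells with equal shares at both depths gave 57.6% and 55.2% after thinning.

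Alternatives for cells were no filter, a stricter filter, Scrublet calls removed, other Leiden resolutions and all filtered cells. For ratios and lists they were thinning, equal weight per cell, centring on the median gene, a total without mitochondrial and ribosomal protein genes, another pseudocount, a higher floor and the mean of ratios within shared clusters. For scores they were other limits and depths. The alternatives added after seeing the data are named in the closing section. Figures were drawn with matplotlib 3.10.9. No file column of counts was left unused, and no differential expression test was run, since a single library per age gives no spread between animals.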

Results

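The data are single-cell RNA sequencing of blood cells sorted as live CD45+ CD11b+ Ly6G+ from young (2 months) and old (24 months) mice labelled male, with 1 library per age. Ly6G marks mouse neutrophils, the short-lived phagocytes of the blood. The young library held 13599 barcodes with 69599479 unique molecular identifiers (UMIs) and a median of 4246 per barcode. The old library held 14334 barcodes with 128826996 UMIs and a median of 7265.5. The number of animals behind each library is not stated. With 1 library per age no test between ages is possible: no p-value is given, and values describe these libraries. Intervals in parentheses are 95% intervals, exact Poisson for UMI counts scaled to the library total (CPM) and exact Clopper-Pearson for shares, and cover counting error only. Values are given as young against old. Xist, the RNA of the inactive X chromosome, stood at 168 against 214 CPM, and the Y-linked Eif2s3y at 0 UMIs in both libraries, against the male label, but the Y-linked Ddx3y had 1322 and 964 UMIs and Uty 14 and 3.

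The purpose stated for the series is to describe senescent neutrophils during aging, so old and young neutrophil-like cells were compared. Neutrophil-like cells made up 76.4% (75.6 to 77.1) of the filtered young cells, 9866 of 12921. In the old library they made up 64.4% (63.5 to 65.2), 8699 of 13517. Their median depth was 4076 UMIs in the young and 7452 in the old library. Classical monocyte-like cells, led by Saa3, Vcan, F13a1 and Ccr2, numbered 2 (0.0155%, 0.00187 to 0.0559) young and 995 (7.36%, 6.93 to 7.81) old. The Ly6G+ gate should remove the other types, so their shares also depend on the sort.

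Non-classical monocyte-like cells numbered 456 (3.53%, 3.22 to 3.86) young and 510 (3.77%, 3.46 to 4.11) old. B cell-like cells numbered 418 and 240, T cell-like 189 and 180 and NK cell-like 202 and 25. Platelet-like cells numbered 351 and 606, erythroid cell-like 122 and 469 and basophil- or mast cell-like 2 and 26. No cluster met the rules for a plasma cell, macrophage, dendritic cell, eosinophil or neutrophil progenitor name. Clusters left unnamed held 1313 young (10.2%) and 1765 old cells (13.1%). Among these, a cluster led by platelet genes (cluster 5) held 909 and 853 cells, and a cluster led by erythroid genes (cluster 15) 112 and 160. A cluster led by dendritic cell genes (cluster 12) held 190 and 329, and a cluster led by B cell genes (cluster 17) 98 and 100. A cluster of 4 young (0.0310%) and 323 old cells (2.39%), led by genes at low level, was kept out by a level minimum set after the data were seen. Neutrophil was the best marker list of clusters 5, 15 and 17, with 10, 9 and 5 of 10 markers detected. It was also that of the low-level cluster, with 9 of 10. The neutrophil-like shares thus leave out cells with neutrophil markers.

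Within neutrophil-like cells, summed markers of other types were detected. Erythroid markers stood at 2180.1 against 2089 CPM, B cell markers at 103 against 36.4, and T cell markers at 25 against 11.3. Platelet markers stood at 100.5 against 170.2, classical monocyte markers at 248 against 689.7 and neutrophil progenitor markers at 7.87 against 34.1 CPM.

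**Figure D1:**
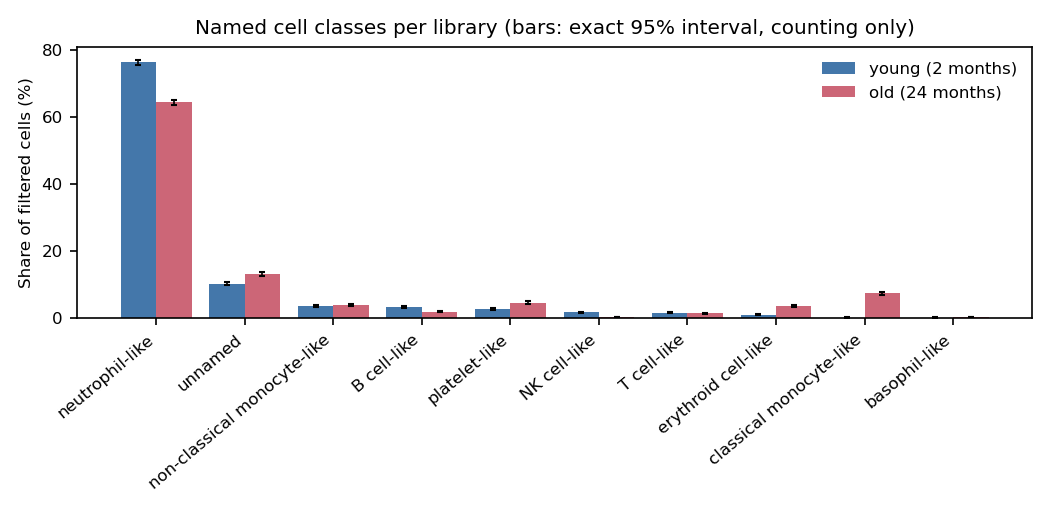
Share of filtered cells (percent) in each named class and in the unnamed clusters, young in blue and old in red, with exact 95% intervals as error bars; a cluster of 2 old cells is left out. Neutrophil-like cells stood at 76.4% and 64.4%, and classical monocyte-like cells at 0.0155% and 7.36%.

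Different clusters held the neutrophil-like cells of the libraries. Clusters 0, 2 and 4 held most young cells (5683, 2008 and 1825), and clusters 1, 3 and 0 most old cells (4078, 2060 and 1480). Clusters 1 and 3 held 29 and 25 young cells, clusters 2 and 4 100 and 228 old cells. Clusters 9, 18 and 19 held 46 and 690, 153 and 14, and 97 and 49 young and old cells. A cluster mostly of 1 library can be that library rather than a state, and the genes that define clusters differ between libraries, so cluster sizes are not compared. Values over all neutrophil-like cells below hold this difference, and values within clusters 0 and 4 follow.

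Over all neutrophil-like cells, specific granule genes were far higher in the old library, whereas interferon-stimulated and immediate early genes were lower. As a list, immediate early genes were not lower within clusters 0 and 4. Ltf, the iron-binding protein of specific granules, was 17.8-fold higher, at 149 (146 to 153) against 2658 (2647 to 2669.8) CPM. Camp, the antimicrobial cathelicidin, was 15-fold higher, at 311 (306 to 317) against 4682 (4667 to 4697) CPM, and Ngp, another granule protein, 17.0-fold, at 516 (509 to 523) against 8775 (8754 to 8796) CPM. Ifit3, an interferon-induced antiviral protein, was 6.57-fold lower, at 59.2 (56.9 to 61.5) against 9.01 (8.35 to 9.70) CPM. The calprotectin genes S100a8 and S100a9 together took 10.8% of young and 29.5% of old UMIs in these cells.

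Since CPM are shares of a total, they depend on such abundant genes. Over 2568 genes at 50 CPM or more the median log2 ratio of old to young was -0.68. This lies beyond 1.5-fold, so most of these genes count as lower in plain ratio. For the lists, values relative to this median gene are given beside the plain ratios. Single genes are mostly given in plain CPM, so a gene described as lower can lie near the median gene. Within cluster 0 the median gene stood at -0.17 and within cluster 4 at -0.21. Among the genes named below, Atf3, Bcl2l11, Btg2, Ccrl2, Cd274, Cxcr4, Hsp90ab1, Il1b, Lmnb1, Mmp8, Nr4a1, Ptgs2, Slc7a11 and Syk had the other direction in the mean of the ratios within clusters 0 and 4.

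Under the naming rule (50 CPM or more in either library, ratios with 1 CPM added), the largest old to young ratio was that of Prok2. It encodes prokineticin 2, a secreted peptide made by neutrophils, and stood at 8.23 (7.41 to 9.12) against 386 (382 to 391) CPM, 46.9-fold higher without the added CPM. Lipg, which encodes endothelial lipase, stood at 0.924 (0.663 to 1.25) against 52.5 (50.9 to 54.1) CPM, and Ggt1, a glutathione-cleaving enzyme, at 2.30 (1.88 to 2.79) against 62.3 (60.5 to 64.1) CPM. Ifitm6, a member of the interferon-induced transmembrane family found in immature neutrophils, stood at 229 (224 to 233) against 3638 (3624 to 3651) CPM. Serpinb1a, an inhibitor of neutrophil serine proteases, was 15.8-fold higher, at 14.8 (13.7 to 16) against 234 (230.3 to 237) CPM, and Acvrl1, a receptor of the TGF-beta family, 17.3-fold, at 5.50 (4.83 to 6.24) against 95.2 (93.0 to 97.4) CPM. Chil3, a chitinase-like secreted protein, stood at 66.9 (64.5 to 69.3) against 948 (941 to 955) CPM. Ly6g, the antigen of the sort itself, was at 103 (99.7 to 106) against 1014 (1007 to 1022) CPM, and Cd177, a neutrophil surface protein, at 73.9 (71.4 to 76.4) against 669 (663 to 675) CPM. These genes and Ltf, Camp and Ngp lay above the median gene by at least 3.84 log2.

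Under the same rule, the lowest ratios belonged to Sugct, a mitochondrial CoA transferase, and to Dmd, which encodes dystrophin. Sugct stood at 886 (878 to 895) against 4.52 (4.06 to 5.02) CPM, and Dmd at 52.6 (50.5 to 54.8) against 0.706 (0.530 to 0.921) CPM. In B cell-like, T cell-like and non-classical monocyte-like cells, too, the old level of Sugct was at most 3.78% of the young. Dock4, an activator of small GTPases, stood at 128 (124 to 131) against 10.4 (9.67 to 11.1) CPM. Egr1, an immediate early transcription factor, was 12.8-fold lower, at 75 (72.5 to 77.6) against 5.87 (5.34 to 6.44) CPM, and Zbtb16, which encodes the transcription factor PLZF, 11.7-fold, at 65.3 (63.0 to 67.8) against 5.59 (5.08 to 6.15) CPM. Pmaip1, the pro-apoptotic protein Noxa, was 11.2-fold lower, at 64.4 (62.0 to 66.8) against 5.72 (5.20 to 6.29) CPM. Slfn5, an interferon-induced schlafen gene, was at 161 (157 to 165) against 23 (21.9 to 24.1) CPM. The other genes of this group were Ccdc146, Chrm3, Creb5, Abhd15 and Zfp53, 6.71-fold to 10.2-fold lower.

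**Figure D2:**
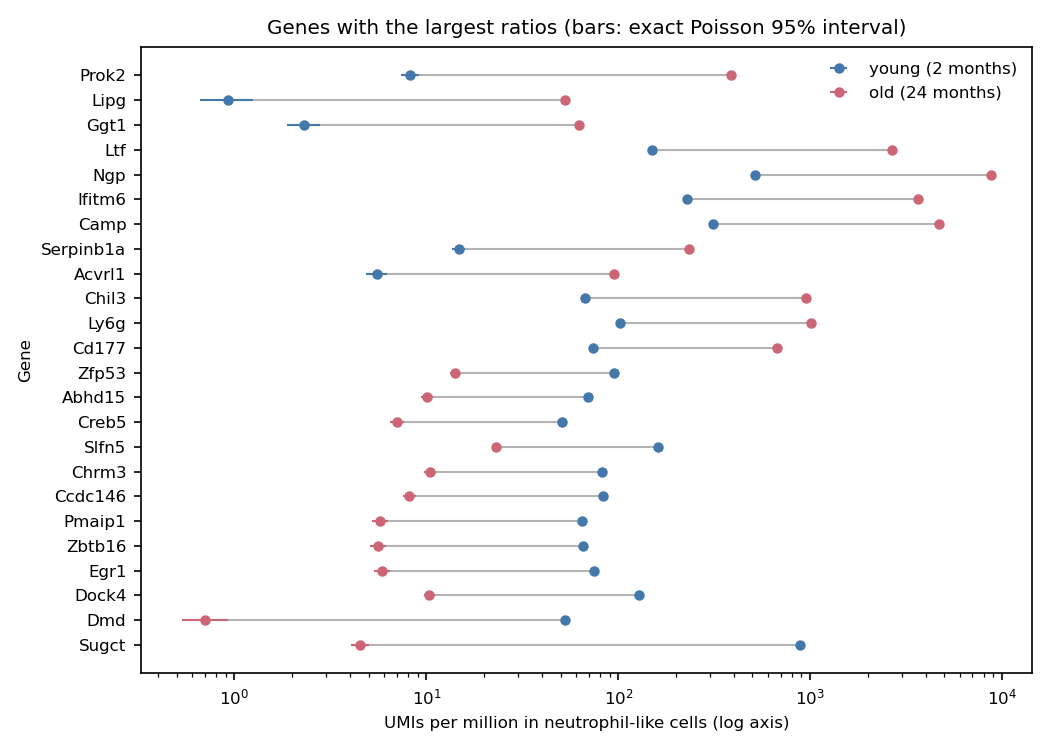
CPM (log axis) in young (blue) and old (red) neutrophil-like cells for the 12 genes with the largest and the 12 with the smallest ratio under the naming rule, with exact Poisson 95% intervals. Prok2 stood at 8.23 and 386 CPM, and Sugct at 886 and 4.52 CPM.

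Positions are from the GENCODE annotation of build GRCm38 (mm10), and each entry is a protein-coding gene. The old-high genes were Prok2 (ENSMUSG00000030069) on chromosome 6 from 99711299 to 99726392, Lipg (ENSMUSG00000053846) on chromosome 18 from 74939322 to 74961263 and Ggt1 (ENSMUSG00000006345) on chromosome 10 from 75561604 to 75586200. The granule genes were Ltf (ENSMUSG00000032496) on chromosome 9 from 111019271 to 111042767, Camp (ENSMUSG00000038357) on chromosome 9 from 109847379 to 109849617 and Ngp (ENSMUSG00000032484) on chromosome 9 from 110419747 to 110423012. They included Ifitm6 (ENSMUSG00000059108) on chromosome 7 from 141015699 to 141017924 and Chil3 (ENSMUSG00000040809) on chromosome 3 from 106147554 to 106167564. Surface genes were Ly6g (ENSMUSG00000022582) on chromosome 15 from 75155240 to 75159126 and Cd177 (ENSMUSG00000052212) on chromosome 7 from 24743983 to 24760311. The young-high genes were Sugct (ENSMUSG00000055137) on chromosome 13 from 16857472 to 17695553 and Dmd (ENSMUSG00000045103) on chromosome X from 82948870 to 85206141. The cytokine genes were Il1b (ENSMUSG00000027398) on chromosome 2 from 129364570 to 129371139 and Cxcl2 (ENSMUSG00000058427) on chromosome 5 from 90903871 to 90905938.

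Neutrophils fill azurophil, specific and gelatinase granules in that order as they mature in the marrow, and transcripts of the early sets are scarce in mature blood neutrophils. The specific granule list was higher almost throughout: of 12 measured members, 11 were higher, 0 lower and 1 within 1.5-fold (relative to the median gene, 12, 0 and 0), with a median of 3.28, a relative median of 3.96 and percentile 100 of 10000 random lists matched on expression. This percentile describes these libraries and is no test. Azurophil granule genes that could be measured went the same way: of 4 measured members, 3 were higher, 0 lower and 1 within 1.5-fold (relative to the median gene, 4, 0 and 0), with a median of 1.94, a relative median of 2.62 and percentile 100. The largest of these ratios was that of Serpinb1a, the protease inhibitor. Mpo, Elane and Ctsg lay under the floor, at 0.418, 3.08 and 0.327 CPM in old neutrophil-like cells, so the list does not cover them. Prtn3, which encodes proteinase 3, stood at 2.86 (2.39 to 3.41) against 13.4 (12.6 to 14.3) CPM, and Ctsc, the protease that activates granule proteases, at 6.97 (6.21 to 7.79) against 30.4 (29.2 to 31.7) CPM. Cebpe, the transcription factor of specific granule genes, stood at 18.5 (17.2 to 19.8) against 57.9 (56.2 to 59.6) CPM, 3.13-fold higher, but at -0.42 log2 with the immature-granule-high cells defined below left out. The specific granule median was 2.17 without those cells, and 0.98 as the mean within shared clusters. These transcripts were found in B cell-like cells too: Ltf stood at 23.4 UMIs per old neutrophil-like cell and at 3.08 per old B cell-like cell.

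The gelatinase granule list was split: of 10 measured members, 4 were higher, 4 lower and 2 within 1.5-fold (relative to the median gene, 5, 1 and 4), with a median of -0.12, a relative median of 0.55 and percentile 96.7. Retnlg, an abundant neutrophil resistin-like gene, was 2.92-fold higher, at 7543 (7518 to 7569) against 21993 (21959.8 to 22026) CPM and Mmp8, a granule collagenase, 2.31-fold, at 919.6 (911 to 929) against 2123 (2113 to 2134) CPM. Mmp8 was lower within both shared clusters, at 876 against 582 CPM and 805 against 674 CPM. Mmp9, the gelatinase, stood at 1235 (1225 to 1245) against 1866 (1857 to 1876) CPM, and Vnn3 at 66.2 (63.9 to 68.7) against 13.9 (13.1 to 14.8) CPM. S100 and secreted antimicrobial genes were higher: of 14 measured members, 9 were higher, 1 lower and 4 within 1.5-fold (relative to the median gene, 12, 1 and 1), with a median of 1.39, a relative median of 2.07 and percentile 99.99. S100a8 stood at 52349.9 (52283 to 52417) against 154206 (154118 to 154294) CPM and S100a9 at 55378 (55309 to 55447) against 141285 (141200.00 to 141369) CPM. Wfdc17 and Wfdc21, secreted whey acidic proteins, stood at 1815 against 6425 CPM and 1151 against 5570.4 CPM. Stefin genes, cysteine protease inhibitors whose close paralogs share reads and are uncertain singly, gave this result: of 7 measured members, 2 were higher, 0 lower and 5 within 1.5-fold (relative to the median gene, 5, 0 and 2), with a median of 0.30, a relative median of 0.98 and percentile 99.55. Granulopoiesis transcription factors went both ways: of 9 measured members, 2 were higher, 4 lower and 3 within 1.5-fold (relative to the median gene, 3, 0 and 6), with a median of -0.32, a relative median of 0.36 and percentile 86.88. Cebpa stood at 18 against 7.07 CPM. Cell cycle genes were few: of 6 measured members, 1 were higher, 2 lower and 3 within 1.5-fold (relative to the median gene, 1, 0 and 5), with a median of -0.31, a relative median of 0.36 and percentile 72.71.

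The question of senescence was addressed by lists of inhibitor, p53 target, secretory and circulation-aged genes, and over all cells none of these stood above the median gene by more than 0.0421 log2 as a group. A list median cannot decide this question where members are expected to move in opposite directions. The inhibitor list holds Lmnb1, which senescent cells lose, and Cdkn1a and Cdkn2a were not among its 7 measured members. Within clusters 0 and 4 the secretory list stood at 0.30 and 0.20 relative to the cluster's median gene, the inhibitor list at 0.10 and -0.0914, the p53 target list at -0.14 and 0.0121 and the circulation-aged list at -0.0230 and -0.0720. The list of cell cycle inhibitors and senescence genes was near the median gene: of 7 measured members, 2 were higher, 4 lower and 1 within 1.5-fold (relative to the median gene, 2, 0 and 5), with a median of -0.76, a relative median of -0.0851 and percentile 40.98. Cdkn1a, which encodes the senescence-linked inhibitor p21, was near absent in both libraries, at 1.17 (0.876 to 1.54) against 2.43 (2.09 to 2.81) CPM. Within clusters 0 and 4 Cdkn1a stood at 1.31 (0.893 to 1.84) against 9.22 (6.93 to 12) CPM and 0.831 (0.334 to 1.71) against 5.26 (1.71 to 12.3) CPM, in old cells at 0.0365 and 0.0219 UMIs per cell, against 0.0833 in old B cell-like cells, which can express it themselves. Cdkn2a, which encodes p16, had 1 UMI in each library, and Cdkn1b, the inhibitor p27, stood at 184 (179.7 to 188) against 99.98 (97.8 to 102) CPM. Lmnb1, the lamin B1 lost in senescent cells, stood at 746 (738 to 754) against 439 (434 to 444) CPM and at -0.0851 log2 relative to the median gene. Plaur, the urokinase receptor used as a senescence surface marker, was 1.60-fold higher, at 320.5 (315 to 326) against 511 (506 to 517) CPM. The p53 targets list held no higher member: of 9 measured members, 0 were higher, 7 lower and 2 within 1.5-fold (relative to the median gene, 0, 0 and 9), with a median of -0.74, a relative median of -0.0623 and percentile 35.7. Btg2, an antiproliferative p53 target, stood at 664 (657 to 672) against 291 (287 to 295) CPM.

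Senescence-associated secretory genes were mixed: of 18 measured members, 6 were higher, 9 lower and 3 within 1.5-fold (relative to the median gene, 7, 4 and 7), with a median of -0.64, a relative median of 0.0421 and percentile 37.73. Il1b, the pro-inflammatory interleukin 1 beta, stood at 2967 (2951 to 2984) against 1568 (1559 to 1577) CPM, and Csf1, the macrophage growth factor, was 6.23-fold lower, at 160.1 (156 to 164) against 25.7 (24.6 to 26.8) CPM. Cxcl2, a chemokine that draws neutrophils, was 2.95-fold higher, at 22.9 (21.5 to 24.4) against 67.5 (65.7 to 69.4) CPM, and Hgf, hepatocyte growth factor, stood at 47.0 (45.0 to 49.1) against 13.9 (13 to 14.7) CPM. Genes of neutrophils that have aged in the circulation were mostly lower: of 11 measured members, 1 were higher, 7 lower and 3 within 1.5-fold (relative to the median gene, 2, 4 and 5), with a median of -0.79, a relative median of -0.11 and percentile 30.77. Cxcr4, the marrow-homing receptor of aged neutrophils, stood at 459 (453 to 465) against 153 (150.1 to 156) CPM. Itga4, an integrin chain, was 3.99-fold lower, at 626 (618 to 633) against 157 (154 to 159.5) CPM. Itgax stood at 50.8 (48.7 to 53) against 8.72 (8.07 to 9.40) CPM and Icam1 at 11.4 (10.4 to 12.4) against 3.03 (2.65 to 3.45) CPM.

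Mature neutrophil receptors stood near the median gene: of 21 measured members, 1 were higher, 12 lower and 8 within 1.5-fold (relative to the median gene, 4, 3 and 14), with a median of -0.66, a relative median of 0.0182 and percentile 58.23. Csf3r, the receptor of the growth factor G-CSF, was 2.95-fold lower, at 4735 (4715 to 4756) against 1606 (1597 to 1615) CPM, and Cd101, a surface protein of mature neutrophils, 4.09-fold, at 507 (500.3 to 514) against 124 (122 to 127) CPM. Cxcr2, the receptor for Cxcl2, stood at 1719 (1706 to 1731) against 992 (985 to 999.5) CPM, at -0.11 log2 relative to the median gene. Itgam, the CD11b antigen of the sort, stood at 696 (688 to 704) against 605 (599.7 to 611) CPM. Phagocytosis and Fc or complement receptor genes held no higher member: of 13 measured members, 0 were higher, 5 lower and 8 within 1.5-fold (relative to the median gene, 2, 1 and 10), with a median of -0.46, a relative median of 0.22 and percentile 75.13. C5ar2, a receptor of complement C5a, was 4.45-fold lower, at 165 (161 to 169) against 37.1 (35.8 to 38.5) CPM, and the kinase Syk stood at 743 against 395 CPM.

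Interferon-stimulated genes were mostly lower: of 31 measured members, 1 were higher, 28 lower and 2 within 1.5-fold (relative to the median gene, 2, 19 and 10), with a median of -1.44, a relative median of -0.76 and percentile 0. Their summed CPM stood at 6004 against 4152, a ratio of 0.69, which is not below the ratio of the median gene. Ifit3 and Ifit3b, neighbours whose reads can be shared and are uncertain singly, stood at 59.2 against 9.01 CPM and 43.6 against 6.38 CPM. As the mean within shared clusters the median of interferon-stimulated genes was 0.0384, which is no result, since these genes define cluster 4. Within cluster 0 alone the list stood at 0.0259 relative to the cluster's median gene. In the 2 shared clusters made without the tested lists it was -0.15 and -0.39 relative to the cluster's median gene. Ifit3b and Ifit3 are among the leading genes of the first of these 2, so it can hold a mix of states. Ifi204, a sensor of DNA, was 5.53-fold lower, at 141 (137 to 144) against 25.4 (24.3 to 26.6) CPM. MHC class I genes, whose H2 members are close paralogs, stood near the median gene: of 14 measured members, 0 were higher, 6 lower and 8 within 1.5-fold (relative to the median gene, 1, 1 and 12), with a median of -0.56, a relative median of 0.12 and percentile 50.79. MHC class II genes were scarce: of 4 measured members, 0 were higher, 1 lower and 3 within 1.5-fold (relative to the median gene, 2, 0 and 2), with a median of -0.12, a relative median of 0.56 and percentile 85.38. NF-kB targets tended lower: of 18 measured members, 1 were higher, 12 lower and 5 within 1.5-fold (relative to the median gene, 2, 6 and 10), with a median of -0.86, a relative median of -0.18 and percentile 11.37. Tnfaip2 stood at 596 (589 to 603) against 234 (231 to 238) CPM and Ccrl2, a chemokine-binding receptor, at 11.4 against 2.82 CPM. Bcl2a1b, of a paralog family that shares reads, stood at 19.9 against 4.97 CPM. Immediate early genes held no higher member over all cells: of 15 measured members, 0 were higher, 13 lower and 2 within 1.5-fold (relative to the median gene, 0, 8 and 7), with a median of -1.29, a relative median of -0.62 and percentile 0.03. Within clusters 0 and 4 the median of immediate early genes was 0.31 and 0.11, and with each gene's ratio averaged over both 0.28, the other direction. Atf3 and Nr4a1, stress-induced transcription factors, stood at 57.9 (55.7 to 60.2) against 14.5 (13.6 to 15.4) CPM and 29.9 (28.3 to 31.5) against 7.54 (6.94 to 8.18) CPM. Heat shock genes stood near the median gene: of 7 measured members, 1 were higher, 2 lower and 4 within 1.5-fold (relative to the median gene, 1, 0 and 6), with a median of -0.49, a relative median of 0.18 and percentile 55.64. Hsp90ab1 stood at 56.4 against 104 CPM.

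Energy metabolism genes lay above the median gene over all cells. Relative to the cluster's median gene, nuclear oxidative phosphorylation genes stood at 0.0844 and 0.157 within clusters 0 and 4. Cytosolic ribosomal protein genes stood at 0.0169 and 0.0254 there, but glycolysis genes at 0.657 and 0.751 and mitochondrially encoded genes at 0.756 and 0.641. Glycolysis genes gave this split: of 19 measured members, 9 were higher, 1 lower and 9 within 1.5-fold (relative to the median gene, 17, 0 and 2), with a median of 0.56, a relative median of 1.24 and percentile 100. Gapdh and Pgk1, enzymes of glycolysis, stood at 811 (803 to 819) against 2033 (2023 to 2043) CPM and 109.9 (107 to 113) against 319 (315 to 323) CPM. Mitochondrially encoded genes were all higher: of 12 measured members, 12 were higher, 0 lower and 0 within 1.5-fold (relative to the median gene, 12, 0 and 0), with a median of 1.40, a relative median of 2.08 and percentile 100. Their share of UMIs in these cells was 0.215% against 0.781%, a measure that also follows cell quality. The nuclear oxidative phosphorylation list was smaller in size of change: of 76 measured members, 12 were higher, 3 lower and 61 within 1.5-fold (relative to the median gene, 54, 0 and 22), with a median of 0.11, a relative median of 0.78 and percentile 100. Ndufa11, of respiratory complex I, stood at 4.73 against 34.0 CPM. Cytosolic ribosomal protein genes were mostly within 1.5-fold in plain ratio: of 79 measured members, 10 were higher, 5 lower and 64 within 1.5-fold (relative to the median gene, 39, 0 and 40), with a median of -0.11, a relative median of 0.57 and percentile 100. Rpsa stood at 87.6 against 233 CPM. Hypoxia response genes were mostly within 1.5-fold in plain ratio: of 10 measured members, 1 were higher, 1 lower and 8 within 1.5-fold (relative to the median gene, 6, 1 and 3), with a median of 0.11, a relative median of 0.79 and percentile 99.64. P4ha1 stood at 14.1 against 28.9 CPM.

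Effector genes were uneven. NADPH oxidase genes, which make the oxidative burst, gave this split: of 7 measured members, 1 were higher, 0 lower and 6 within 1.5-fold (relative to the median gene, 5, 0 and 2), with a median of 0.35, a relative median of 1.03 and percentile 98.78. Cybb, the catalytic subunit, was 7.56-fold higher, at 69.4 (67.0 to 71.9) against 525 (519.6 to 529.9) CPM. Extracellular trap and lytic death genes went both ways: of 7 measured members, 1 were higher, 2 lower and 4 within 1.5-fold (relative to the median gene, 4, 1 and 2), with a median of 0.13, a relative median of 0.81 and percentile 99.19. Nlrp3, the inflammasome sensor, was 3.81-fold lower, at 332 (326 to 337) against 87.0 (84.9 to 89.1) CPM, and its adaptor Pycard 2.28-fold higher, at 21.8 (20.4 to 23.2) against 49.6 (48.0 to 51.2) CPM. Eicosanoid synthesis genes went both ways as well: of 7 measured members, 4 were higher, 3 lower and 0 within 1.5-fold (relative to the median gene, 4, 1 and 2), with a median of 0.64, a relative median of 1.32 and percentile 99.89. Alox5ap, Lta4h and Ltb4r1, of leukotriene synthesis and sensing, stood at 1571 against 2471 CPM, 24.9 against 94.9 CPM and 73.0 against 238 CPM. Ptgs2, the prostaglandin enzyme, was 4.85-fold lower, at 54.9 (52.7 to 57.1) against 11.3 (10.6 to 12.1) CPM. Immunosuppressive neutrophil genes were split: of 9 measured members, 2 were higher, 4 lower and 3 within 1.5-fold (relative to the median gene, 3, 3 and 3), with a median of -0.54, a relative median of 0.14 and percentile 69.12. Nos2, the inducible nitric oxide synthase, stood at 0.203 (0.0928 to 0.385) against 13.5 (12.7 to 14.4) CPM, from 9 young and 1033 old UMIs, and Cd274, which encodes PD-L1, at 54.1 (52.0 to 56.3) against 15.1 (14.2 to 16) CPM. Cd274 was higher within both shared clusters, at 34.2 (32 to 36.6) against 64.7 (58.4 to 71.6) CPM and 112 (105 to 119) against 167 (142 to 195) CPM.

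Survival genes stood near the median gene: of 8 measured members, 1 were higher, 5 lower and 2 within 1.5-fold (relative to the median gene, 1, 2 and 5), with a median of -0.71, a relative median of -0.0323 and percentile 40.51. Bcl2l1, which encodes Bcl-xL, was 1.94-fold higher, at 39.1 (37.3 to 41.0) against 76.0 (74.1 to 78.0) CPM. Pro-apoptotic genes did too: of 12 measured members, 0 were higher, 8 lower and 4 within 1.5-fold (relative to the median gene, 2, 2 and 8), with a median of -0.73, a relative median of -0.0510 and percentile 25.12. Bcl2l11 stood at 66.7 against 27.2 CPM and Fas, a death receptor, at 142 against 76.0 CPM. Iron handling and ferroptosis genes held no higher member: of 10 measured members, 0 were higher, 5 lower and 5 within 1.5-fold (relative to the median gene, 0, 1 and 9), with a median of -0.60, a relative median of 0.0762 and percentile 44.61. Slc40a1, the iron exporter ferroportin, was 2.78-fold lower, at 722 (714 to 730.2) against 259.5 (256 to 263) CPM, and Slc7a11, a cystine transporter, stood at 312 (307 to 317) against 151 (148 to 154) CPM. Antioxidant enzyme genes were uneven: of 14 measured members, 5 were higher, 4 lower and 5 within 1.5-fold (relative to the median gene, 7, 2 and 5), with a median of 0.0427, a relative median of 0.72 and percentile 99.14. Gclm, of glutathione synthesis, was 5.95-fold higher, at 20.7 (19.4 to 22.1) against 123 (121 to 126) CPM, and Sod1 stood at 28.0 against 8.04 CPM. Lipid handling genes went both ways: of 10 measured members, 3 were higher, 5 lower and 2 within 1.5-fold (relative to the median gene, 3, 3 and 4), with a median of -0.69, a relative median of -0.0130 and percentile 41.44. Abcg1, a cholesterol exporter, stood at 117 against 28.1 CPM. Lysosome and autophagy genes were mostly within 1.5-fold: of 21 measured members, 0 were higher, 5 lower and 16 within 1.5-fold (relative to the median gene, 4, 3 and 14), with a median of -0.46, a relative median of 0.22 and percentile 85.72. Gm2a, a lysosomal activator protein, stood at 444 against 138 CPM. Circadian clock genes gave the following: of 6 measured members, 0 were higher, 3 lower and 3 within 1.5-fold (relative to the median gene, 1, 0 and 5), with a median of -0.68, a relative median of -0.00242 and percentile 44.5. Nfil3 stood at 51.2 against 67.6 CPM.

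**Figure D3:**
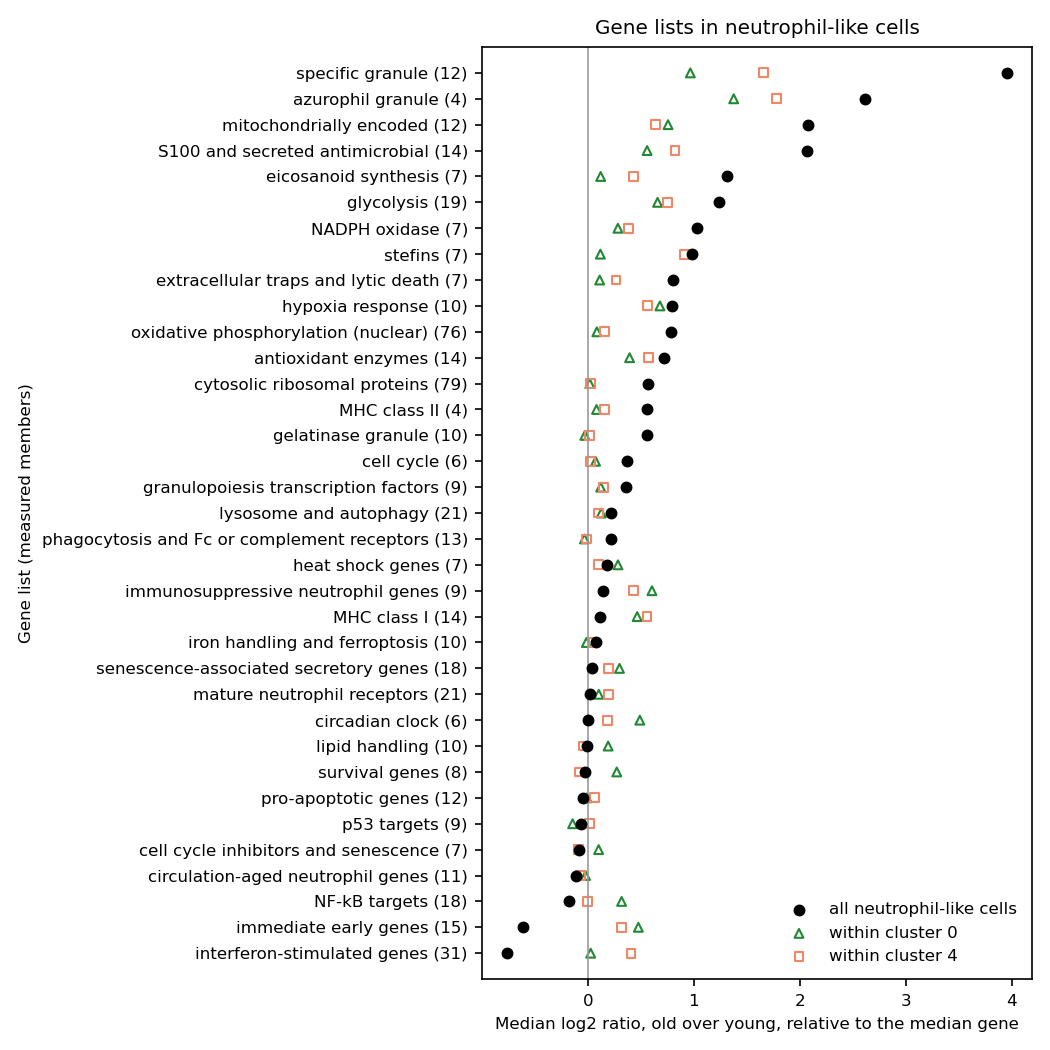
Median log2 ratio of old to young relative to the median gene for each of the 35 gene lists (measured members in parentheses), over all neutrophil-like cells (black) and within clusters 0 (green) and 4 (orange). Specific granule genes stood at 3.96 over all cells and at 0.97 and 1.66 within the clusters, and interferon-stimulated genes at -0.76 over all cells. Their value in cluster 4, which they define, is no result.

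Per-cell scores showed the granule difference in a range of high-scoring cells and in the rest of the old cells. With every neutrophil-like cell thinned to 1000 UMIs, cells with at least 10 UMIs of Ltf, Camp, Ngp, Lcn2 and Chil3 together made up 1.52% (1.29 to 1.78, 149 of 9811 cells) of young and 35.3% (34.3 to 36.4, 3066 of 8676 cells) of old cells. The shares of immature-granule-high cells were 6.42% against 62.5% at limit 5 and 0.663% against 19.3% at limit 20. The background was 0 of 418 young B cell-like cells, and 2.08% of old ones, and 0 of 186 young and 3.89% of old T cell-like cells. The young B cell-like count of 0 allows up to 0.718% (3 counts). Median depth of the B cell-like cells before thinning was 6392.5 and 8586.5 UMIs. Without thinning the shares were 18.4% and 84.7%. Cells within 1 UMI of the limit numbered 61 young and 840 old. Old cells of this range held medians of 22 immature granule, 6 mature receptor and 3 interferon-stimulated UMIs. Young ones held 16, 7 and 3. Outside this range, which is cut on the same UMIs, young cells held a median of 0 and old cells of 4 immature granule UMIs. In B cell-like cells the median was 0 in the young and 1 in the old library.

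Cells with at least 5 interferon-stimulated UMIs out of 1000 made up 49.0% (48.0 to 50, 4807 of 9811 cells) of young and 38.6% (37.6 to 39.6, 3347 of 8676 cells) of old cells. In B cell-like cells, which respond to interferon themselves, the shares were 6.94% and 1.67%, and in T cell-like cells 19.9% and 13.3%. Without thinning they were 96.4% and 98.6% of neutrophil-like cells, the other direction, in deeper old cells. The shares of interferon-high cells were 73.2% against 71.5% at limit 3, 17.9% against 6.47% at limit 10, and 37.6% against 38.1% in cluster 0 alone, where the difference was not seen. Cells within 1 UMI of the limit numbered 2701 and 3060. Young cells of this range held medians of 8 interferon-stimulated, 0 immature granule and 16 mature receptor UMIs. Old ones held 6, 6 and 10. Left out as too shallow were 55 young and 23 old cells. The interferon score is a share of each cell's UMIs, and its mean was 6.18 in young and 4.47 in old cells. Such shares depend on S100a8 and S100a9, which took 10.8% of young and 29.5% of old UMIs. The list's summed CPM did not fall below the median gene, so the score does not show a fall beyond it. Both scores are ranges of a score and not cell types.

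Il1b, Slc7a11 and Ptgs2, lower over all cells in plain ratio, were higher in the old cells of the shared clusters. The intervals of Ptgs2 overlapped in cluster 4. Over all cells their log2 ratios were -0.92, -1.04 and -2.18, where the median gene stood at -0.68. Il1b and Slc7a11 thus lay within 1.5-fold of the median gene over all cells. Slc7a11 and Ptgs2 are among the leading genes of cluster 0. Cells can have been placed there for them, so their values within it do not show a change within a state. Clusters 0 (5683 and 1480 young and old cells) and 4 (1825 and 228) had at least 200 cells of each library. Il1b stood at 2931 (2909.6 to 2952) against 5328 (5269 to 5387) CPM within cluster 0 and at 2985 (2948 to 3022) against 4873 (4734 to 5016) CPM within cluster 4. Slc7a11 stood at 345 (338 to 353) against 602 (582 to 622) CPM and 284 (273 to 296) against 499 (455 to 546) CPM, and Ptgs2 at 50.4 (47.6 to 53.2) against 91.7 (84.1 to 99.8) CPM and 50.2 (45.5 to 55.2) against 58.9 (44.5 to 76.4) CPM. Cxcl2, Plaur and Bcl2l1, higher over all cells, were higher within both clusters too. They were also higher per old B cell-like cell. Plaur stood there at 0.809 against 1.87 UMIs per cell, and within cluster 0 at 1.43 against 2.75. Cxcl2 stood at 26.8 (24.8 to 28.9) against 254 (242 to 268) CPM within cluster 0 and at 15.1 (12.6 to 17.9) against 82.0 (64.8 to 102) CPM within cluster 4, Plaur at 332 (325 to 339) against 694 (673 to 716) CPM and 321 (309 to 334) against 642 (592 to 695) CPM, and Bcl2l1 at 41.9 (39.4 to 44.6) against 93.4 (85.7 to 102) CPM and 37.5 (33.5 to 41.9) against 95.7 (77.0 to 117) CPM. Not every inflammatory gene named here was higher there: Csf1 stood at 122 against 122 CPM and 172 against 119.8 CPM, Nlrp3 at 339.5 against 326 CPM and 345 against 279 CPM, and Icam1 at 8.12 against 8.20 CPM and 12 against 7.36 CPM. Ccrl2, lower over all cells, stood at 8.41 (7.30 to 9.64) against 15.9 (12.8 to 19.5) CPM and 16 (13.4 to 19.0) against 22.1 (13.7 to 33.7) CPM, and Bcl2a1b at 15.7 (14.2 to 17.4) against 26.0 (22 to 30.4) CPM and 19.6 (16.7 to 22.8) against 9.46 (4.33 to 18) CPM. The NF-kB targets list had a median of 0.15 within cluster 0 and -0.21 within cluster 4, and the senescence-associated secretory genes of 0.13 and -0.00906.

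Cd101, Csf3r and Sugct kept within the clusters the direction seen over all cells. Sugct and Cd101 are among the leading genes of cluster 0, which limits their values within it, but not of cluster 4. Cd101 stood at 528 against 406 CPM within cluster 0 and 481 against 297 CPM within cluster 4, Csf3r at 4824 against 3748 CPM and 4852 against 3429.9 CPM, and Sugct at 889 against 7.85 CPM and 843 against 4.2 CPM. Cxcr4, lower over all cells, did not, at 432 against 512 CPM and 457 against 489 CPM. Of the 58 named genes at least 1.5-fold higher over all cells, 52 were above 0 within cluster 0 and 56 within cluster 4. Among these, 10 and 14 exceeded the UMIs per old B cell-like cell, and 42 and 42 did not. That level also holds what B cells express themselves. Of the 80 named genes at least 1.5-fold lower over all cells, 54 and 61 were below 0, as were 71.5% and 71.2% of all 2568 genes at 50 CPM or more. Ltf, which B cells should lack, stood at 0.518 UMIs per old cell within cluster 0 against 3.08 in old B cell-like cells. Free RNA that enters all cells alike would not exceed the lower level, so the B cell-like level is no measure of free RNA in cluster 0. Interferon-stimulated genes define cluster 4, so their values within it are no result.

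**Figure D4:**
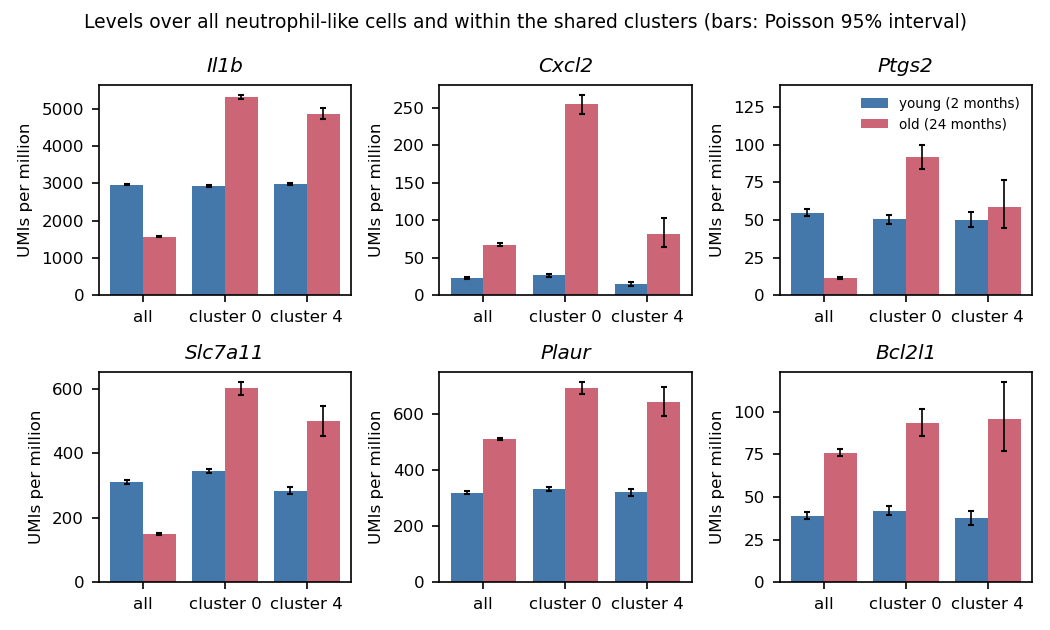
CPM in young (blue) and old (red) cells over all neutrophil-like cells and within clusters 0 and 4, with exact Poisson 95% intervals. Il1b stood at 2967 and 1568 CPM over all cells, but at 2931 and 5328 CPM within cluster 0. These CPM are not relative to the median gene, from which Il1b differed by less than 1.5-fold over all cells. Ptgs2 and Slc7a11 are among the leading genes of cluster 0, which limits their values there.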

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

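Chosen only after the result was seen were the tests of neutrophil states for each pattern, of UMIs per cell for the granule genes and of a few dominant genes for the interferon-stimulated genes.

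Signals outside the main measurement drew attention. Classical monocyte-like cells made up 7.36% of filtered old cells, where a count of 0 would allow 0.0222%, with 2 such cells in the young library. Their median depth was 19265 UMIs, against 7452 in old neutrophil-like cells. They held Ccr2 at 1042 CPM, F13a1 at 903, Saa3 at 888 and Prtn3 at 272. Ly6g stood at 131 and S100a8 at 21507 CPM, against 1014 and 154206 in old neutrophil-like cells. Doublets with neutrophils were not excluded, since the caller had not worked, and the Ly6G+ gate should leave such cells out. An unnamed cluster led by low-level genes such as Nkain2 and Dlgap1 held 323 old cells.

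Xist, the RNA of the inactive X chromosome, stood at 168 CPM of filtered young cells and 214 CPM of old ones, although both libraries are labelled male. It was seen in 87.3% of young and 95.4% of old B cell-like cells, and in 18.2% and 47.7% of neutrophil-like cells. The Y-linked gene Eif2s3y had 0 UMIs in each library, which (as 3 counts) allows 0.0452 CPM in the young and 0.0237 in the old. Kdm5d had 0 and 5, Uty 14 and 3, and Ddx3y 1322 and 964 UMIs.

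Specific granule genes were higher in the old neutrophil-like cells. Free RNA as the whole source was argued against, since the level in old B cell-like cells made up 15.9% of the difference (median of 11 higher members), although non-classical monocyte-like cells held Camp at 57.3% of the neutrophil-like level. With every cell thinned the list's median stayed at 2.91, so the greater weight of deeper cells in the sum was not the whole source. Thinning keeps each gene's expected share of a cell's UMIs, so it cannot decide on other effects of more UMIs per cell. Different shares of neutrophil states alone cannot be told apart from a change within states. In clusters made without the tested lists, at most 1 of the higher members exceeded the B cell-like level. Ltf stood at 0.534 and 0.480 UMIs per old cell in these clusters, against 3.08 per old B cell-like cell. Free RNA that enters all cells alike would not exceed those lower levels. The B cell-like level is thus no measure of it there, and the comparison cannot decide. Age, and any difference between the libraries that goes with it, stay open as untested.

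Interferon-stimulated genes were lower in the old neutrophil-like cells. A few genes taking a larger share of UMIs was argued against, for the typical member, by -0.76 relative to the median gene. This does not cover the list's summed CPM, whose ratio of 0.69 was not below that of the median gene. A like difference in all cells of the old library cannot be told apart from one in neutrophil-like cells: the list's median relative to the median gene was -0.52 in B cell-like and -0.67 in non-classical monocyte-like cells, but 0.0283 in T cell-like cells (-0.0931 to 0.21), where a value above -0.2 in 2 of the 3 types was set beforehand as evidence against. Different shares of neutrophil states alone cannot be told apart from a change within states: clusters made without the tested lists gave -0.39 and -0.15, between the bounds set for either reading. Cluster 0 of the main clustering gave 0.0259. Age, and any difference between the libraries that goes with it, stay open as untested.

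Sugct was almost absent from the old library. Different shares of neutrophil states were argued against, since it lay at -6.48 or less relative to the median gene within both shared clusters. Sugct is among the leading genes of cluster 0, which limits its value there, but not of cluster 4, where it stood at -7.14. A candidate explanation is a variant that differs between the mice of the libraries. In B cell-like, T cell-like and non-classical monocyte-like cells the old level was at most 3.78% of the young. Young levels per cell there were 1.91, 3.50 and 2.50 times those expected if free Sugct RNA entered as S100a8 did. Other transcripts would give other multiples. In young B cell-like cells S100a8 stood at 20.2% of the neutrophil-like level, Camp at 3.59% and Csf3r at 25.2%. The multiples are thus uncertain. Old levels of Dmd were 5.78%, 1.12% and 0.522% of the young in B cell-like, T cell-like and non-classical monocyte-like cells. No sequence reads were at hand to look for such a variant, and age stays open as untested.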

How the results depend on the processing

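Chosen only after seeing the data were the alternatives that included mixed and low-level clusters, removed the highest Scrublet scores or cells with other types' markers, used the largest shared cluster alone, or left out immature-granule-high cells. For lists, so were the stricter filter, equal weight per cell and another total. Removing Scrublet calls changed 1 cell and shows nothing about doublets. Where a value moved or reversed, the cause was not tested.

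The old minus young share of neutrophil-like cells was -12.0 points. It was -13.7 with no filter, -9.90 and -13.8 at resolutions 0.3 and 1.0, -10.1 with mixed and low-level clusters, and -10.4 without the highest Scrublet scores. For interferon-high cells -10.4 points became -1.70 at limit 3, and reversed to 2.25 with no thinning and 0.50 in the largest shared cluster. For immature-granule-high cells 33.8 points became 35.7 at 500 UMIs, 66.3 with no thinning, 56.0 and 18.6 at limits 5 and 20, and 2.47 in the largest shared cluster.

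Medians of the lists specific granule, cell cycle inhibitors and senescence, senescence-associated secretory genes, and interferon-stimulated genes were 3.28, -0.76, -0.64 and -1.44. They were 3.10, -0.31, -0.44 and -1.24 over all filtered cells and 2.91, -0.43, -0.36 and -1.17 with every cell thinned. With each cell counted alike they were 2.98, -0.46, -0.35 and -1.16, and with immature-granule-high cells left out 2.17, -0.30, -0.30 and -1.08. Centred on the median gene they were 3.96, -0.0851, 0.0421 and -0.76, the secretory list reversed. The mean of ratios within shared clusters gave 0.98, -0.18, -0.0171 and 0.0384. The interferon list reversed there, but this rests on cluster 4, which these genes define, and is no result. Relative to the cluster's median gene it stood at 0.0259 within cluster 0. Clusters made without the tested lists had it at -0.15 and -0.39, the first of them led by Ifit3b and Ifit3 among others. At a floor of 20 CPM the granule, senescence and secretory medians were 3.16, -0.58 and -0.89, and MHC class II had no member left. With mixed and low-level clusters the interferon median was -1.37. Other lists whose median lay at least 1.5-fold from 0 and reversed were iron handling and ferroptosis (0.0762) and mature neutrophil receptors (0.0182) when centred, and circadian clock (0.18) and immediate early genes (0.28) within shared clusters. Changes of sign in lists nearer 0, such as MHC class I, were not counted.

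Of the 153 genes under the naming rule 22 reversed as the mean within shared clusters: Atf3 0.74, B2m 0.12, Bcl2l11 0.0102, Btg2 0.19, Ccrl2 0.64, Cd274 0.74, Cxcr4 0.17, Fosb 0.54, H2-K1 0.36, H2-Q4 0.20, Hsp90aa1 0.0398, Hsp90ab1 -0.0685, Il1b 0.78, Irf5 0.0454, Lmnb1 0.15, Mmp8 -0.42, Nlrc5 0.48, Nr4a1 0.39, Per1 0.28, Ptgs2 0.54, Slc7a11 0.81, Syk 0.0941. Elsewhere, Cebpa reversed over all filtered cells (0.11), Cebpe without immature-granule-high cells (-0.42) and Hsp90aa1 when centred (0.0501). No other named gene at least 1.5-fold apart changed direction. All 153 stayed within counting error under the stricter filter, 150 without cells holding other types' markers, 151 with another total, 138 with 0.1 CPM added, and 133 without the highest scores. Beyond counting error moved 127 with thinning, 127 with each cell counted alike, 121 over all filtered cells and 151 when centred. Depth limits genes such as Cdkn1a, with 52 young and 186 old UMIs.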

Other observations

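The values here were chosen only after the main results were seen. Specific granule genes were higher in other old cells of the sort too, with list medians relative to the median gene of 3.28 log2 in non-classical monocyte-like, 3.13 in B cell-like and 5.12 in T cell-like cells. B and T cells should lack these genes, so the values do not show expression in monocytes. Camp, a granule antimicrobial peptide, stood at 23.1 (19.1 to 27.8) against 2142 (2104 to 2180.4) CPM in non-classical monocyte-like cells. In B cell-like cells it stood at 6.73 against 367 and in T cell-like cells at 5.29 against 623 CPM. S100a8, an abundant neutrophil transcript, held 20.2% and 16.8% of the neutrophil-like level per B cell-like cell, and 32.8% and 33.8% per non-classical monocyte-like cell.

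In old classical monocyte-like cells, where doublets were not excluded, Elane, which encodes neutrophil elastase, stood at 57.5 CPM (54.3 to 60.9), with a UMI in 18.5% of cells, against 3.08 CPM in old neutrophil-like cells. Mpo and Ctsg, of azurophil granules, had a UMI in 6.93% and 7.14% of cells. Mki67, a proliferation gene, stood at 32.1 against 8.36 CPM. Vcan, an extracellular matrix proteoglycan of monocytes, and Fn1, which encodes fibronectin, stood at 563 and 775 CPM, against 4.30 and 9.27 CPM in old neutrophil-like cells.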
